A study of Mus musculus with 14 samples.

How the data were processed

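Chromatin accessibility was measured by ATAC-seq, which cuts and tags open DNA with a transposase, in nuclei from 50 mg of frozen liver of 14 female mice. Mice carrying a floxed matrin-3 gene (Matr3, encoding a nuclear matrix protein that binds RNA and DNA) were compared with littermates that also carried an Albumin-Cre transgene, which deletes the floxed part in hepatocytes (liver-specific knockout). The animals received chow or a high-fat diet with 60 kcal% fat from 7 weeks of age for 16 weeks, per the labels' protocols. A 12 h fast before collection is described for the high-fat animals, and the feeding state of the chow animals is not given in the sources used here. The groups held 3 knockout and 3 floxed mice on chow, and 4 knockout and 4 floxed mice on the high-fat diet. The titles number the females of each diet singly, so each library is read as 1 animal.

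The authors deposited 1 table per diet with whole-number counts of aligned reads per interval and library. Both tables use mm10 coordinates, per the labels, and positions here are 1-based. There were 88203 intervals for chow and 105801 for the high-fat diet, all 501 bp wide and not overlapping one another within a table. Interval names begin with the genotype they were called in: 44011 chow intervals came from knockout calls and 44192 from floxed calls, against 52391 and 53410 in the high-fat table. Trim Galore 0.6.7, Bowtie2 2.4.2, MACS2 2.2.7.1, bedtools, HOMER 4.11, DESeq2 and ChIPseeker are named in the submitters' processing notes, without their roles. How the authors treated duplicate and mitochondrial reads, whether reads were shifted for the transposase's cutting offset, and whether calls were made per library or on pooled libraries are not given in the sources used here. Because intervals were chosen on the same libraries that are compared, weak regions open in a single animal may be under-represented. The high-fat columns match the labels of single samples. The chow columns name the genotype and a number, but the chow labels use other names, so each chow column was used as a member of its group with no label of its own.

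Counts per library summed to between 15.5 and 35 M in the chow table, and to between 7.59 and 10.4 M in the high-fat table. Every pair of libraries of a group differed by more than counting noise (chi-square over degrees of freedom 2.49 at the least), so no library was counted as a repeat of another. Totals cover reads within intervals only.

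Each table was fitted alone with edgeR 4.0.16 in R 4.3.3: TMM factors, the filterByExpr filter (which removed no interval), a quasi-likelihood fit of genotype, and Benjamini-Hochberg adjustment over all intervals at 0.05. An interval is called if it passes that threshold. Fold changes are log2 of knockout over floxed, errors of fold changes are standard errors (SE) from the fit, and levels are counts scaled to library size (CPM) with SD. The genotype effect was compared between diets on intervals of both tables matched 1 to 1 with at least 50% overlap, in 1 fit of all 14 libraries, testing the high-fat effect minus the chow effect. Diet itself was not tested, because each diet sits in a table of its own. Similarity of the separate fold changes was measured by correlation across matched intervals, which are not independent replicates. DESeq2 1.42.0 and limma 3.58.1 (voom with quality weights) served as alternatives. On simulated counts drawn from these means and dispersions, edgeR recovered 65.7% of intervals changed by 1 on the log2 scale and 100% of those changed by 2 in the chow table, with 4 false calls. In the high-fat table it recovered 55.2% and 100%, with 5 false calls. For the difference between diets the shares were 31.2% and 97.2%, with 6 false calls over 73945 intervals. Changes of 0.5 were recovered in 0%, 2.99% and 0% of cases, so smaller effects were mostly below what these libraries can show. The simulation drew every interval independently, with dispersions from a trend. It holds no variation shared between the intervals of a liver, so it does not give the rate of false calls in the real libraries.

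Intervals were assigned to the nearest protein-coding gene within 50000 bp, using the RefSeq table of GRCm38.p6, the assembly that mm10 names, with 21896 protein-coding genes. That table gives gene bounds without strand or exons. Transcription start sites, promoters, exons and introns could therefore not be told apart, and "gene end" below means within 1000 bp of either bound of a gene. The remaining intervals are called gene body or intergenic. Gene ends held 22.3% of chow and 20.4% of high-fat intervals, against 5.53% and 5.69% after shifting the intervals by 100000 bp. Corrections for GC content and the search for sequence motifs need a genome sequence and were not run, and interval width does not vary.

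Before the data were examined, the groups, the fits, the alternatives, the rule for named genes and 26 gene lists were fixed. The lists were CAR and PXR xenobiotic targets, fatty acid and triglyceride synthesis, lipid droplet and fatty acid uptake, fatty acid oxidation and ketogenesis, cholesterol synthesis and uptake, bile acid synthesis and transport, gluconeogenesis and fasting response, unfolded protein and integrated stress response, oxidative stress NRF2 targets, inflammation and acute phase, AP-1 and immediate early genes, p53 and cell cycle, fetal liver and imprinted genes, female-biased and male-biased liver genes, the circadian clock, periportal and pericentral zonation, hepatocyte transcription factors, DNA sensing and interferon, and markers of stellate cells, Kupffer cells, lymphocytes, neutrophils, sinusoidal endothelium and biliary cells. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 26 lists of a comparison, and again with an estimated correlation and with fry. A list gene counts as higher if it has a called higher interval and no called lower one, and the reverse. Its other intervals may lie the other way. Named genes are Matr3, then up to 8 genes per direction with the largest called change among intervals at or above the median level whose groups did not overlap, and up to 3 genes per direction of each list that passed or held a call. The difference between diets names the 5 intervals per direction with the smallest p, and up to 2 members each of the fatty acid synthesis and xenobiotic lists are named even if not called. Genes named outside this rule are marked as chosen after their values were seen.

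The labels number the animals within each group. In the chow table the deviations from the group means of same-numbered columns correlated at 0.184, 0.533 and 0.189, although knockout 1 correlated more with floxed 3 (0.278), and the numbers come from the column names. All 3 exceed 0.1, so a fit with the number as a block is given beside the chow result and beside the difference between diets where it changes a call. Alternatives covered normalisation, low-count filters, the test, thresholds, sex chromosomes, the overlap rule, the reach of gene assignment, the replicate block and leaving out each library.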

Results

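Accessible chromatin was profiled in liver nuclei of 14 female mice, comparing liver-specific matrin-3 knockouts with floxed littermates on chow (3 of each) and on a high-fat diet (4 of each). Reads within intervals, in megareads (M), totalled 31.3, 15.5 and 35 M in chow knockouts 1, 2 and 3, and 31.4, 17.1 and 33.2 M in chow floxed animals 1, 2 and 3. High-fat knockouts 1 to 4 gave 9.46, 8.98, 7.59 and 7.92 M. High-fat floxed animals 1 to 4 gave 8.92, 10.4, 7.8 and 8.75 M. Spread between animals was moderate, with a common biological coefficient of variation of 0.187 on chow and 0.17 on the high-fat diet. Fold changes below are knockout over floxed on the log2 scale.

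The targeted gene, Matr3, carried accessible intervals only around 1 of its ends on chromosome 18, and these did not differ between genotypes. The strongest, at 35561987 to 35562487 in the chow table, held 27.3 ± 3.03 CPM in floxed and 27.8 ± 2.86 CPM in knockout livers (SD, n = 3), a log2 fold change of 0.03 (SE 0.14). Its high-fat counterpart, at 35561998 to 35562498, held 30.3 ± 5.79 and 30.1 ± 1.86 CPM (SD, n = 4), a log2 fold change of -0.01 (SE 0.12). The edgeR adjusted p of all 5 Matr3 intervals lay between 0.579 and 0.987. The position of the deleted part is not given in the sources used here, so these intervals do not check the labels.

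On chow, the intervals called by edgeR were mostly lower in knockout than in floxed livers. The largest fall among the named intervals that passed was in C3, the central complement component. An interval in its gene body (chromosome 17, 57224717 to 57225217) held 28.1 ± 6.25 CPM in floxed and 4.3 ± 1.88 CPM in knockout livers (SD, n = 3), a log2 fold change of -2.69 (SE 0.29). Serpina3k, a serine protease inhibitor made by hepatocytes, fell by 2.21 (SE 0.26; chromosome 12, 104341977 to 104342477), from 23.5 ± 8.14 to 5.21 ± 0.742 CPM. Lifr, the receptor of leukaemia inhibitory factor, fell by 2.19 (SE 0.24; chromosome 15, 7142672 to 7143172), from 15.1 ± 4.64 to 3.38 ± 0.235 CPM. Phlda1 fell by 2.10 (SE 0.27) at a gene end, and Gpr108, which lies beside C3, fell by 1.04 (SE 0.14). One interval rose, between genes and 10.7 kb from Alb, the albumin gene (chromosome 5, 90449902 to 90450402). It held 18.7 ± 3.04 CPM in floxed and 45.8 ± 7.03 CPM in knockout livers, a log2 fold change of 1.29 (SE 0.16).

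The edgeR quasi-likelihood test called 20 of 88203 chow intervals, 1 higher and 19 lower. Its adjusted p was 0.0261 for C3, 0.0261 for Lifr, 0.0383 for Serpina3k, 0.041 for Alb, 0.048 for Phlda1 and 0.048 for Gpr108. C3 held 11 of the called intervals, of 43 assigned to it, Serpina3k 3 and Phlda1 2. Fabp5, chosen after its values were seen, held the 1 call outside the naming rule (a log2 fold change of -2.59). All 20 separated the groups completely, as did 11.7% of all intervals, against 10% by chance. The count moved with single animals. edgeR called 0 intervals without knockout 1 (3730 at an unadjusted p under 0.05), where the adjusted p of the named genes reached 0.205 to 0.256, and 0 without floxed 1 (4371). It called 7 without knockout 2, 7 without floxed 3, 43 without knockout 3 and 604 without floxed 2. The shallow libraries numbered 2 stood apart from the rest on the first principal component (42.2% of the variance), and 333 intervals passed without both. DESeq2 called 544 intervals and limma-voom 677, and the fit with the replicate number as a block called 126, 8 higher and 118 lower.

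Apart from Alb, no list member passed the test on chow over all intervals. Camera with a preset correlation passed 10 of the 26 lists, with 4 passing without knockout 1 and 6 without knockout 3. None passed with an estimated correlation: the adjusted p with an estimated correlation was 0.888 for fatty acid and triglyceride synthesis and 0.841 for the other 9. The periportal list passed downward (camera adjusted p = 1.3e-05, median log2 fold change -0.33 over 444 intervals), as did gluconeogenesis and fasting genes (1.3e-05, median -0.16). So did hepatocyte transcription factors (0.00022, median -0.08) and fatty acid and triglyceride synthesis (0.0447, median -0.14). With 1 interval per gene the direction of the periportal, transcription factor and fatty acid lists turned (camera adjusted p = 0.859, 0.857 and 0.918). Their strongest members did not pass edgeR: Igf1, a growth hormone target, at -1.71 (adjusted p = 0.115), Onecut1, a hepatocyte transcription factor, at -3.41 (0.125), Foxa2, a pioneer factor of liver genes, at -1.22 (0.0958), and Agpat2, an enzyme of triglyceride synthesis, at -1.14 (0.22). CAR and PXR xenobiotic targets passed upward (camera adjusted p = 0.00022, median 0.18), with Cyp2b13 at 1.71 (edgeR adjusted p = 0.31) and Cyp2b9 at 1.48 (0.352). Alas1, the first enzyme of haem synthesis, held 6.79 ± 3.75 CPM in floxed and 1.79 ± 0.249 CPM in knockout livers (edgeR adjusted p = 0.173, n = 3). The NRF2 targets (camera adjusted p = 0.0113, median 0.11) and the circadian clock (0.05, median 0.09) also passed upward, the clock list no longer with the replicate block (0.0504). Markers of other liver cells passed downward: sinusoidal endothelium (camera adjusted p = 7.06e-05, median -0.16), Kupffer cells (0.0216, median -0.13) and neutrophils (0.0262, median -0.31). With the replicate block stellate cells and extracellular matrix passed as well (0.0255, against 0.0624 without it).

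Adjusted over the list alone, 1 gene rose and 4 fell among hepatocyte transcription factors, 1 rose and 1 fell each among periportal and among gluconeogenesis genes. In the same way 2 rose and 3 fell among male-biased genes, 3 bile acid genes fell, and 1 gene fell in each of the inflammation, pericentral and Kupffer cell lists. The other 18 lists had no such gene on chow. The lists that did not pass camera on chow were cholesterol synthesis (adjusted p = 0.059), p53 and cell cycle (0.0944), lymphocytes (0.11), fetal liver (0.193), DNA sensing and interferon (0.419), female-biased genes (0.449), biliary cells (0.449), AP-1 (0.723), inflammation (0.81) and male-biased genes (0.954). Lipid droplets, fatty acid oxidation, bile acids, the unfolded protein response and pericentral genes each had 0.842. In 8 of these (lipid droplets, fatty acid oxidation, bile acids, unfolded protein response, inflammation, AP-1, male-biased and pericentral genes) the median, the mean and the test differed in sign.

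On the high-fat diet, accessibility changed in both directions. Egfr, the receptor of epidermal growth factor, rose across its locus. Its named interval (chromosome 11, 16918758 to 16919258) went from 3.4 ± 0.58 CPM in floxed to 11.9 ± 4.95 CPM in knockout livers (SD, n = 4), a log2 fold change of 1.90 (SE 0.25). Of 136 intervals assigned to the gene, 73 passed. Nr4a1, an orphan nuclear receptor induced by hormonal and stress signals, rose by 1.60 (SE 0.22; chromosome 15, 101274232 to 101274732) with 14 of 31 intervals passing. Igfbp1, an insulin-repressed binding protein of insulin-like growth factors, rose by 1.45 (SE 0.22) with 6 of 19. Car3, carbonic anhydrase 3, fell by 2.43 (SE 0.27; chromosome 3, 14872425 to 14872925), from 14.7 ± 5.69 to 2.88 ± 1.01 CPM, with 12 of 18 intervals passing. Gsta3, a glutathione S-transferase, fell by 1.53 (SE 0.24) with 19 of 39 intervals. Cyp2b13, a cytochrome P450 of female liver, fell by 1.44 (SE 0.23) with 26 of 50, and Ttr, the thyroid hormone carrier transthyretin, by 1.65 (SE 0.24) with 10 of 23.

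The edgeR test called 795 of 105801 high-fat intervals, 474 higher and 321 lower, near 205 genes with higher and 132 with lower intervals. DESeq2 called 829 and limma-voom 656. The adjusted p was 0.000126 for Egfr, 0.000227 for Nr4a1, 0.000677 for Igfbp1, 1.41e-05 for Car3, 0.000724 for Gsta3, 0.000785 for Cyp2b13 and 0.00032 for Ttr. Of the called intervals 647 separated the groups completely, against 5.3% of all intervals and 2.86% by chance. The ranking of changes covers only called intervals at or above the median level whose groups did not overlap. Among these the other genes with the largest gains included Rnase4, a secreted ribonuclease (1.81), Agxt, a peroxisomal aminotransferase (1.57), and Uap1l1 (1.47). Clasp1, a microtubule-binding protein, went from 4.73 ± 1.78 to 13.1 ± 4.51 CPM, and Hip1r from 3.96 ± 1.17 to 10.8 ± 3.14 CPM (edgeR adjusted p = 0.00152 and 0.00135). Under the same limits, the other genes with the largest losses were Dlec1 (-1.93), Dock6 (-1.62), Clec2d (-1.59) and Trf, encoding transferrin, the iron carrier of plasma (-1.23). Agxt did not pass without knockout 4 (adjusted p = 0.0575), and Trf not without knockout 4 (0.064) or floxed 4 (0.0563). The count was 304 without knockout 4, 326 without floxed 4, 359 without knockout 3, 437 without floxed 2 and 1189 without floxed 3. Higher intervals made up 48.4% of calls without floxed 3, against 59.6% with all libraries. On the first principal component (25.7% of the variance) knockout 1 lay at -4.98 and floxed 3 at 18.9, against 12.2 to 73.4 for the other knockouts and -75 to -41 for the other floxed livers.

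**Figure D1:**
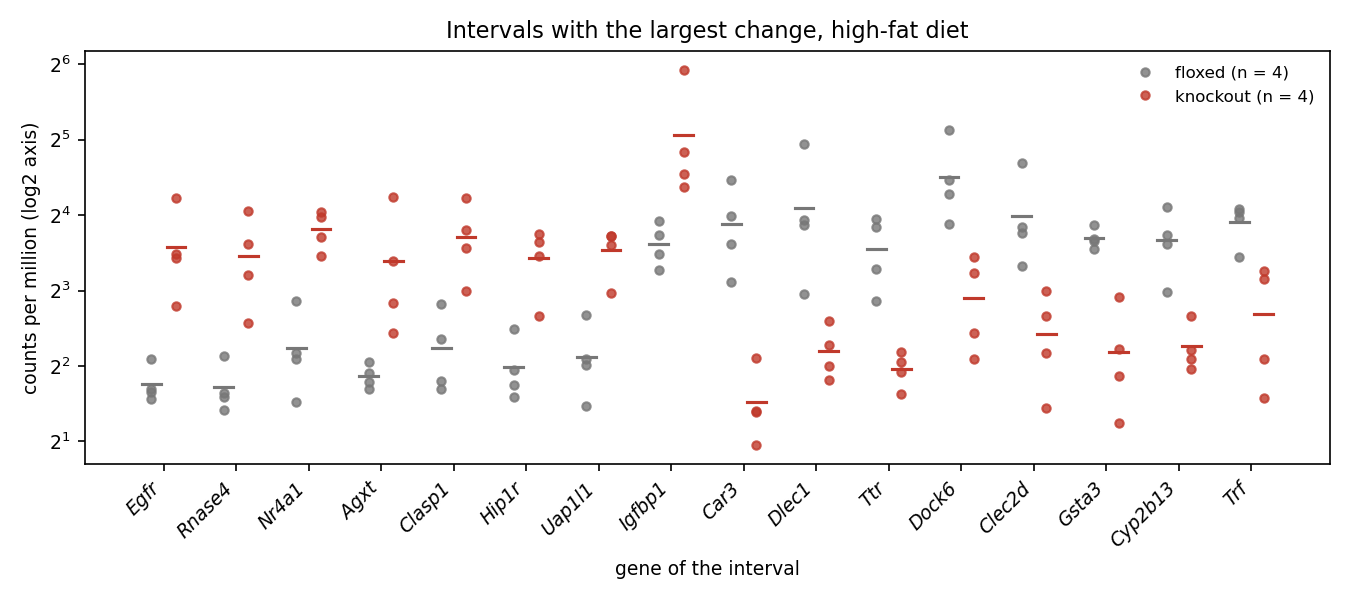
CPM (counts scaled to library size), on a log2 axis, in the interval of each of the 16 genes named for a large change on the high-fat diet. They had the largest called changes per direction among intervals at or above the median level whose groups did not overlap. Points are single livers (4 floxed, grey; 4 knockout, red) and bars are group means; in every gene shown all 4 knockout livers lie on 1 side of all 4 floxed livers, with Igfbp1 reaching a mean of 33.4 CPM in knockouts and Car3 a mean of 2.88 CPM.

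Genes expressed more in female than in male liver lost accessibility in high-fat knockouts: 10 of 26 list genes fell and 0 rose (14 fell and 1 rose when adjusted over the list alone). Cyp3a41a fell by 1.56 (SE 0.25, edgeR adjusted p = 0.000877), Cyp2b9 by 0.88 (SE 0.15, adjusted p = 0.00143) and Sult2a1, a steroid sulfotransferase, by 0.99 (SE 0.18, adjusted p = 0.00457). The list passed camera at an adjusted p of 6.83e-25, with a median log2 fold change of -0.38 over 334 intervals, and had an adjusted p = 0.257 with an estimated correlation. Kupffer cell markers lay higher in the same knockout livers (median 0.16). Male-biased genes did not pass (camera adjusted p = 0.184): 1 of 25 genes, Mup20, fell by 0.83 (edgeR adjusted p = 0.0162) and 0 rose, with 1 lower and 0 higher when adjusted over the list alone. Without knockout 3, knockout 4, floxed 2 or floxed 4, Mup20 had an adjusted p of 0.0806, 0.0843, 0.0531 and 0.078.

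CAR and PXR targets, the genes of xenobiotic clearance, passed downward too, and share Cyp2b9, Cyp2b13 and Sult2a1 with the female-biased list. Of 35 genes 6 fell and 1 rose (17 fell and 3 rose when adjusted over the list alone). The list had a camera adjusted p of 4.91e-19 and an adjusted p = 0.428 with an estimated correlation. The gene counted as higher was Ahr, the dioxin receptor, by 1 of 22 intervals, whose median log2 fold change was -0.0247. That interval rose by 1.30 (SE 0.23, edgeR adjusted p = 0.00296). NRF2 targets passed downward (camera adjusted p = 0.000114, median -0.12, adjusted p = 0.209 with an estimated correlation), with 1 of 14 genes lower (3 when adjusted over the list alone). The strongest interval of that gene, Osgin1, lost its call without floxed 4 (edgeR adjusted p = 0.2).

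Lipid genes moved in both directions. In fatty acid and triglyceride synthesis 6 of 25 genes fell and 1 rose (11 and 3 when adjusted over the list alone). Fasn, the fatty acid synthase, fell by 1.91 (SE 0.29, edgeR adjusted p = 0.000631) and Fads2, a fatty acid desaturase, by 1.07 (SE 0.20, adjusted p = 0.00469). Lpin1, a phosphatidate phosphatase that also acts as a coactivator, rose by 0.87 (SE 0.18, adjusted p = 0.013). Lpin1 had an adjusted p of 0.113 without knockout 4 and 0.0715 without floxed 4. The list passed camera downward (adjusted p = 0.00433, and adjusted p = 0.663 with an estimated correlation). Cholesterol synthesis passed downward with a median of -0.25 (camera adjusted p = 6.49e-15, adjusted p = 0.209 with an estimated correlation), with 6 of 20 genes lower and 0 higher when adjusted over the list alone. Among lipid droplet genes 2 of 21 rose and 1 fell (4 and 1 when adjusted over the list alone). Plin4, a lipid droplet coat protein, rose by 1.42 (edgeR adjusted p = 0.00675, but 0.095 without knockout 4 and 0.0528 without floxed 4). The strongest intervals of Hilpda, which rose, and Apob, which fell, lost their call without knockout 4 too (edgeR adjusted p = 0.0869 and 0.107). That list and fatty acid oxidation, with 1 of 28 genes lower (1 higher and 3 lower when adjusted over the list alone), did not pass camera (adjusted p = 0.7 and 0.168).

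In bile acid synthesis and transport, Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 1.44 (SE 0.28, edgeR adjusted p = 0.00682), and of 20 genes 1 rose and 1 fell (1 and 1 when adjusted over the list alone). The gene that rose, Abcb4, had an edgeR adjusted p of up to 0.215 with 1 library left out (knockout 4). The list passed downward (camera adjusted p = 0.000211, adjusted p = 0.663 with an estimated correlation). Gluconeogenesis and fasting genes did not pass (0.325) but held 2 genes that rose, Nr4a1 and Igfbp1, and 2 that fell, among 19 (4 and 5 when adjusted over the list alone). The genes counted as lower, Pck1 and Tat, each held 1 called interval, of 35 and 33. The median log2 fold change over all their intervals was -0.1 and 0.0587. Both called intervals lost their call without knockout 3 (edgeR adjusted p = 0.0771 and 0.244), knockout 4 (0.0508 and 0.2), floxed 2 (0.0654 and 0.176) or floxed 4 (0.0513 and 0.217). The periportal list passed upward (camera adjusted p = 0.0124, adjusted p = 0.799 with an estimated correlation) and 3 of its 19 genes rose. Another 2 fell and 1, Alb, had intervals in both directions (3, 4 and 2 when adjusted over the list alone). Apoa4, an apolipoprotein, rose by 1.42 (edgeR adjusted p = 0.00478, but 0.0544 without knockout 4). Without that library the intervals of Pck1 and Ass1 that fell lost their call too (edgeR adjusted p = 0.0508 and 0.194). Ass1 counts as lower by 1 of 79 intervals, whose median log2 fold change was 0.689, so the locus as a whole did not fall. The pericentral list passed downward (camera adjusted p = 0.00377, adjusted p = 0.606 with an estimated correlation). In it 2 of 22 genes fell and 1 had intervals in both directions (2 higher, 3 lower and 1 in both when adjusted over the list alone). Cyp2e1, which fell, lost its call without knockout 4 (edgeR adjusted p = 0.234). Hepatocyte transcription factors and the circadian clock passed downward (camera adjusted p = 0.00101 and 0.00573, each with an adjusted p = 0.663 with an estimated correlation). Each held 1 higher and 1 lower gene. Without floxed 4 the strongest intervals of Nfix and Ppara among the factors lost their call (edgeR adjusted p = 0.145 and 0.162), as did those of Bhlhe40 and Ciart in the clock (0.133 and 0.11). Adjusted over the list alone these were 0 and 0 for the factors and 1 and 1 for the clock.

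Kupffer cell markers passed upward on the high-fat diet (camera adjusted p = 0.000114, median log2 fold change 0.16 over 107 intervals, adjusted p = 0.275 with an estimated correlation). No single gene of its 24 was called, over all intervals or when adjusted over the list alone. The other cell type lists did not pass: neutrophils (camera adjusted p = 0.8, with median and mean of opposite sign), lymphocytes (0.7), sinusoidal endothelium (0.368), biliary cells (0.325) and stellate cells with extracellular matrix (0.209). Nor did inflammation (0.0698, 2 of 31 genes higher, also 2 when adjusted over the list alone), AP-1 (0.0594), the unfolded protein response (0.7), p53 and cell cycle (0.588), fetal liver (0.179, 1 of 11 genes higher, 2 when adjusted over the list alone) or DNA sensing and interferon (0.252). The intervals of the inflammation genes, Orm2 and Saa2, both lost their call without knockout 2 (edgeR adjusted p = 0.14 and 0.281), knockout 4 (0.0568 and 0.0701), floxed 2 (0.132 and 0.163) or floxed 4 (0.139 and 0.16). The fetal liver gene, Igf2bp3, lost its call when any single library except floxed 3 was left out (edgeR adjusted p = 0.0724 to 0.157). Over all intervals the remaining lists held 1 called gene, the endothelial receptor Eng (-1.18, edgeR adjusted p = 0.0445, up to 0.181 without floxed 1), and none when adjusted over the list alone. With 1 interval per gene, camera passed 2 lists on this diet in place of 11.

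Albumin had intervals in both directions. The interval 10.8 kb from Alb rose on the high-fat diet too, from 18.3 ± 2.68 CPM in floxed to 48.8 ± 5.92 CPM in knockout livers (SD, n = 4), a log2 fold change of 1.42 (SE 0.12, edgeR adjusted p = 8.96e-08). The gain did not differ detectably between diets (difference 0.16, SE 0.19, unadjusted p = 0.409 in the joint edgeR fit). Of the 19 intervals inside Alb, 17 were called on the high-fat diet. The median log2 fold change inside the gene was -0.82 on the high-fat diet and -0.21 on chow.

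**Figure D2:**
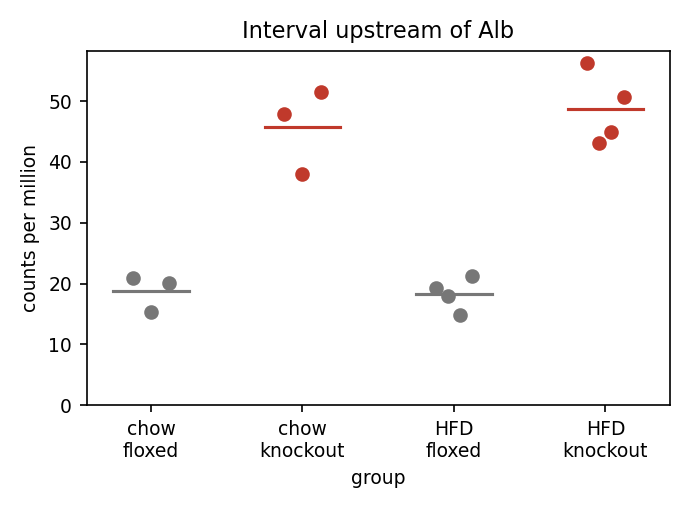
CPM in the interval upstream of Alb for each liver, by diet and genotype, with bars at the group means. Floxed livers lie between 14.8 and 21.2 CPM and knockout livers between 38 and 56.2 CPM on both diets.

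Intervals that rose on the high-fat diet lay away from gene ends. Of the 474 higher intervals 9.28% lay within 1000 bp of a gene end, against 20.5% of uncalled intervals (odds ratio 0.397, two-sided Fisher's exact test p = 7.18e-11). Of the 321 lower intervals 18.1% did (odds ratio 0.858, Fisher's exact p = 0.332), and the direction turned within 3000 bp (odds ratio 1.35, exact p = 0.00905). On chow 10.5% of the 19 lower intervals lay at gene ends against 22.3% of uncalled ones (odds ratio 0.41, Fisher's exact p = 0.28). This direction also turned within 3000 bp (odds ratio 1.11, exact p = 0.813), and the single higher interval did not lie there (exact p = 1). Neighbouring intervals are not independent, so these p-values are too small.

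The genotype effect was compared directly between diets on 73945 matched intervals. Egfr showed the widest contrast among the 10 named intervals. An interval in its gene body (chromosome 11, 16795772 to 16796272) stood at -1.88 on chow (9.2 ± 3.89 CPM floxed, 2.57 ± 0.394 CPM knockout, SD, n = 3). On the high-fat diet it rose by 1.21 (4.03 ± 1.89 and 8.94 ± 1.22 CPM, SD, n = 4), a difference of 3.11 (SE 0.43). Gadd45g, a stress-induced growth regulator, differed by 2.94 (SE 0.38), Serpina3k by 2.94 (SE 0.44), C3 by 1.92 (SE 0.29) and Zmiz1 by 1.69 (SE 0.25), all with a higher fold change on the high-fat diet. Car3 differed by -2.82 (SE 0.32), from 0.87 on chow to -1.97 on the high-fat diet, and Cyp2b13 by -3.00 (SE 0.49), from 1.71 to -1.32. Ttr (-1.44, SE 0.20), Gsta3 (-1.52, SE 0.26) and Lrrc69 (-1.76, SE 0.31) also had a lower fold change on the high-fat diet.

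The joint edgeR fit called 135 intervals near 38 genes, 99 with a higher and 36 with a lower fold change on the high-fat diet. The adjusted p was 0.000304 for Car3, 0.00111 for Gadd45g, 0.00193 for Egfr and Ttr, 0.00277 for C3, Serpina3k and Zmiz1, 0.00445 for Cyp2b13, 0.00666 for Gsta3 and 0.0089 for Lrrc69. Fold changes had opposite signs on the 2 diets in 124 of the 135. Of the 135, 48 lay at Egfr, with a median of -1.87 on chow and 1.05 on the high-fat diet. Choosing intervals by a large difference favours opposite signs, so 124 is not a count of established reversals. In the separate fits 0 matched intervals were called in opposite directions. At their named intervals Serpina3k (edgeR adjusted p = 0.096 on chow, 0.538 on the high-fat diet) and Gsta3 (0.219, 0.0843) passed on neither diet. On chow the named Egfr, Car3 and Cyp2b13 intervals did not pass (0.121, 0.302 and 0.31). Over the whole Egfr locus 143 of 144 chow intervals lay below 0 (smallest edgeR adjusted p 0.0872), and 134 of 136 high-fat intervals above 0. The count was 82 without chow knockout 1, 89 without high-fat floxed 4 and 370 without chow floxed 2, and 301 with the replicate block. Diet and table coincide, so this contrast can also hold differences between the 2 sets of libraries.

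**Figure D3:**
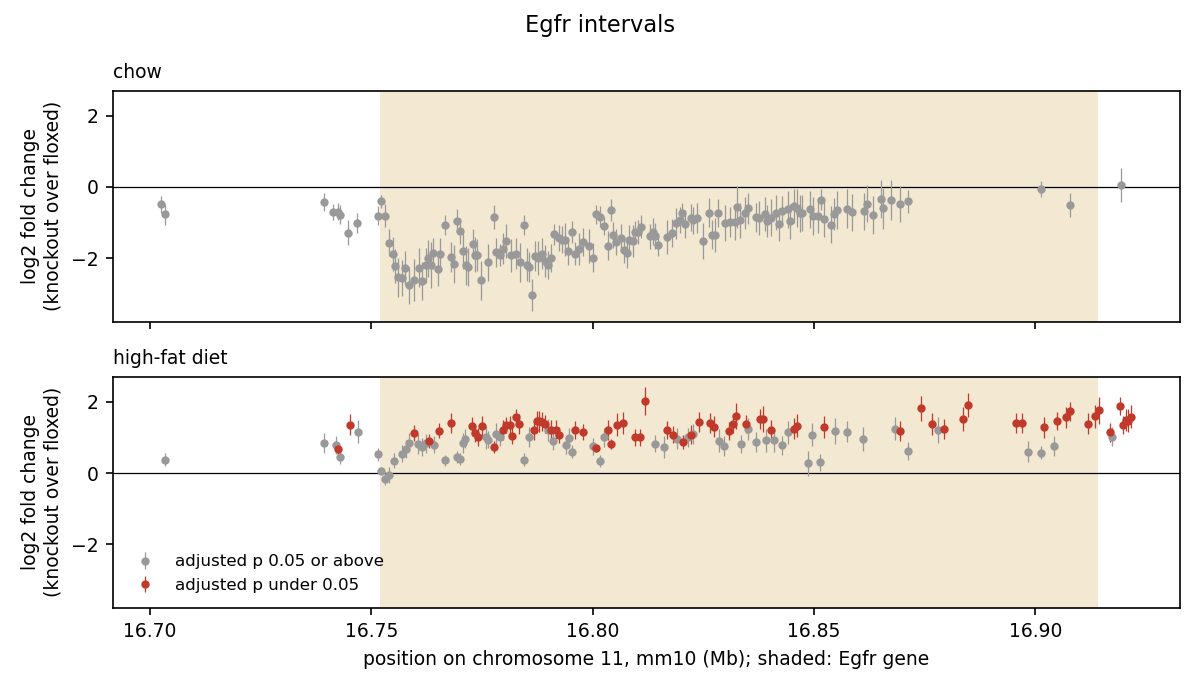
Log2 fold change, knockout over floxed, of each interval assigned to Egfr against its position on chromosome 11, on chow (3 against 3 livers) and on the high-fat diet (4 against 4), with vertical lines for 1 SE. Red marks an adjusted p under 0.05 within a diet and the shaded span is the gene; the median is -1.26 over 144 chow intervals and 1.11 over 136 high-fat intervals.

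Across all matched intervals the 2 genotype effects were close to unrelated (Pearson r 0.0372, Spearman rho 0.0686, across intervals, which are not independent replicates), and 52.8% had the same sign. Over the 441 intervals called in either table r was -0.166, although 51.9% of them had the same sign. This set holds neighbouring intervals of single genes, among them Egfr, and r without Egfr was not computed. The overlap of calls was 1 interval higher on both diets, the one upstream of Alb, with 0.00283 intervals by chance (Fisher's exact test p = 0.00283), and 1 lower on both with 0.0387 by chance (p = 0.038). At an unadjusted p under 0.05 in both edgeR fits, 287 intervals were lower on both diets (115 by chance), 175 higher on both (91.6 by chance), 198 lower on chow and higher on the high-fat diet (95.5 by chance), and 127 higher on chow and lower on the high-fat diet (110 by chance).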

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

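All tests in this part, apart from the edgeR fits of each diet and of the difference between diets, were chosen after the results were seen. Among high-fat groups of 4 livers, 8 of 230 groups looked at (3.48%) held a liver far from the other 3 by Dixon's ratio, where chance gives about 1 in 20. Floxed 1 stood apart at Slco1a1 (3.6 CPM, next 2.11), Orm2 (5.06, next 3.46), Igf2bp3 (1.13, next 2.96) and Vwf (3.49, next 4.38). Floxed 3 stood apart at Igf2 (9.65 CPM, next 13.7) and Mup1 (5.13, next 9.44). Knockout 1 stood apart at Uap1l1 (7.85 CPM, next 12.1) and knockout 4 at Igfbp1 (65.6, next 39.2).

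The genotype effect differed between diets, by the joint edgeR fit, at the 5 named intervals in each direction. These have the smallest p with 1 interval kept per gene. The high-fat minus chow log2 fold change was 2.94 at Gadd45g, 3.11 at Egfr, 1.92 at C3, 2.94 at Serpina3k and 1.69 at Zmiz1, and -2.82 at Car3, -1.44 at Ttr, -3.00 at Cyp2b13, -1.52 at Gsta3 and -1.76 at Lrrc69. Of the 100 pairs of chow and high-fat splits drawn, 3 gave as many calls as the real 135, the real pair included, with 304 as the highest other value. Splitting within each diet stands for no genotype effect on either diet. These splits therefore cannot tell a difference between diets from a genotype effect on 1 diet alone or an equal effect on both. The pair with 304 calls keeps the real high-fat groups with their sign turned, so its calls include the high-fat genotype effect itself.

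For the opposite effect at Egfr, weighed first, a wrong genotype label on a chow library is argued against by the interval with the smallest adjusted p on the high-fat diet, upstream of Alb (14.8 to 21.2 CPM in high-fat floxed and 43.1 to 56.2 CPM in high-fat knockout livers). Against these levels 0 chow libraries lay on the other genotype's side, and each was at least 4.87 high-fat SD from the other genotype's mean. The shallow chow libraries numbered 2 do not carry it, since the median difference over the 48 Egfr intervals was 3.44 without both of them and 2.95 with them. A feeding state that differed between chow animals may contribute: accessibility summed over Pck1, a fasting-induced gene, varied 5.8-fold between the highest and lowest chow library (1.63-fold on the high-fat diet). That cannot be told apart from an effect of diet, because no source used here gives the feeding state of the chow animals. Summed Egfr signal also varied widely within the chow floxed group (790 to 1610 CPM), but stayed above that of every chow knockout (403 to 713 CPM). Summed Pck1 signal overlapped between the genotypes on chow (98.7 to 375 CPM in knockouts, 105 to 573 CPM in floxed). The spread of Pck1 alone therefore does not account for the separation at Egfr.

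For the fall of female-biased genes in high-fat knockouts, weighed second, the X chromosome cannot decide whether a male animal was among the knockouts. Its share of counts in the lowest knockout library was 0.984 of the floxed mean. The silenced X of females adds little open chromatin, however, so a male need not stand out by this share. A lower share of hepatocytes stays open: markers of other cell types moved apart most, relative to SE, between Kupffer cells and lymphocytes (0.125 on the log2 scale, SE 0.0267), but 2 of 35 splits of the same livers, the real one included, gave as large a ratio for some pair of cell types (exact p = 0.0571), and the periportal median of 0.0876 covers genes that went both ways. A shift towards the male pattern would need a gain of male-biased genes, and none was seen on average (mean -0.0365, SE 0.0578 over 25 genes). That SE treats genes as replicates and holds no spread between animals, so it cannot exclude a gain. A direct effect of matrin-3 loss or of the metabolic state of these animals stays open and was not tested.

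The interval upstream of Alb was weighed last. Opening of the whole gene by a native enhancer is argued against by the fall inside Alb on the high-fat diet (median log2 fold change -0.82). Extra copies of albumin regulatory DNA carried by the Albumin-Cre transgene, which the breeding scheme gives to the knockouts, are a candidate explanation. The gain was alike on both diets, and the few neighbouring upstream intervals did not share it. Their median log2 fold change was -0.195 on chow (3 intervals, -0.236 to 0.213) and -0.30 on the high-fat diet (2 intervals, -0.625 to 0.02). The interval at the start of Alb was not among them. It lay higher in knockouts but did not pass edgeR. Its log2 fold change was 0.611 on chow (SE 0.316, adjusted p = 0.756) and 0.335 on the high-fat diet (SE 0.176, adjusted p = 0.534). A smaller gain there is therefore not excluded. Mapped reads of the transgene junctions would be needed to test the transgene explanation further, and an effect of matrin-3 on the interval upstream of Alb stays open.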

How the results depend on the processing

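The fits leaving out both chow libraries numbered 2, the leave-one-out values of list counts and of the correlation between diets, and the block for lists were added after seeing the data. On chow the 20 calls became 45 with TMM factors from the most abundant intervals, 544 with DESeq2, 677 with limma-voom, 13 without sex chromosomes, 126 with the replicate block, 333 without both libraries numbered 2, 0 at an adjusted p of 0.01 (5972 at an unadjusted p under 0.05) and 74 at 0.1, and ranged from 0 (without knockout 1 or floxed 1) to 604 (without floxed 2). The 795 high-fat calls became 482 with a mean count of at least 50, 271 at an adjusted p of 0.01, 1395 at 0.1 and 468 with an absolute log2 fold change of at least 1, and ranged from 304 (without knockout 4) to 1189 (without floxed 3). On the high-fat diet the deviations of same-numbered animals correlated at 0.0676, 0.131, 0.177 and -0.0105. Not all exceed 0.1, and whether the number pairs these animals stays open. With the replicate block the high-fat count was 1420, and not every animal correlated best with its own number. The 135 differences between diets became 283 with DESeq2, 452 from the separate fits, 301 with the replicate block, 397 without both chow libraries numbered 2 and 223 at an adjusted p of 0.1, and ranged from 82 (without chow knockout 1) to 370 (without chow floxed 2). The correlation between diets turned to -0.166 over intervals called in either table, of which 51.9% had the same sign. Over all matched intervals it ranged from 0.00561 (without high-fat floxed 1) to 0.0822 (without chow knockout 1). The 10 chow lists became 0 with an estimated correlation, 3 at gene ends, 0 with fry and 0 with 1 interval per gene, and ranged from 4 (without knockout 1) to 12 (without floxed 3). The 11 high-fat lists became 0 with an estimated correlation, 0 with fry and 2 with 1 interval per gene, and ranged from 11 to 14 (without knockout 2). Direction turned on chow for periportal genes at gene ends (adjusted p = 0.737) and with 1 interval per gene (0.859), for hepatocyte transcription factors with 1 interval per gene (0.857), and for fatty acid synthesis with 1 interval per gene (0.918) and without both libraries numbered 2 (0.148). The share of lower intervals at gene ends turned within 3000 bp (Fisher's exact p = 0.813 on chow, 0.00905 on the high-fat diet). The cause of these changes was not tested, except that fewer calls at stricter thresholds follow from the thresholds. Matr3 log2 fold changes stayed without a call, from -0.04 to 0.12 and -0.26 to 0.08 on chow and from -0.54 to -0.12, -0.11 to 0.11 and -0.50 to -0.35 on the high-fat diet when single libraries were left out.

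Of the values of single named intervals under other settings, on chow 548 kept their side of the threshold, 2 lost and 33 gained a call, and on the high-fat diet 1061 kept it, 29 lost and 18 gained a call, with 0 turning direction in called intervals. Leaving out single libraries, 24 chow and 111 high-fat values lost a call. All 10 named differences between diets kept their call in every setting, 88 values, and with each library left out, 140 values. The replicate block changed the call of the circadian and stellate cell lists on chow and of no other list. Corrections for GC content and width, alone or with the replicate block, and the motif tests were not run, for want of a genome sequence here. Changes of 0.5 on the log2 scale were mostly below what either table can show.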

Other observations

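The tests over other splits, the groups of distant intervals and the genes of this part were chosen after the results were seen, while the edgeR and camera fits they rest on were planned. On the high-fat diet, 74 called intervals lay over 50000 bp from any protein-coding gene, 62 of them higher in knockouts. The densest group lay on chromosome 13 between 52180359 and 52194802, 310 kb from the nearest protein-coding gene, Diras2. It held 16 called intervals, all 16 higher, with log2 fold changes from 1.18 to 3.38 and a smallest edgeR adjusted p of 1.59e-05. The 4 chow intervals in the same span had a median log2 fold change of -0.44.

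Outside the naming rule, and chosen after their values were seen, several high-fat genes held runs of intervals moving together by edgeR: Ces1d, a carboxylesterase, with 10 of 29 lower, Bhmt, an enzyme of methionine metabolism, with 6 of 28 lower, Mat1a, which makes S-adenosylmethionine, with 9 of 37 higher, Insig2, a brake on sterol synthesis, with 8 of 36 higher, and Lepr, the leptin receptor, with 5 of 20 higher.

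Pck1, a fasting-induced gene, varied between chow livers without following genotype. Summed over its intervals, it held 370, 375 and 98.7 CPM in chow knockouts 1, 2 and 3, and 573, 105 and 383 CPM in floxed 1, 2 and 3.

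How often other splits of the same livers gave a result as large was counted for each summary. On chow the 10 splits are too few for a share under 0.05: the real split gave 20 calls and the highest other 16 (1 of 10 as large), and 10 lists passed camera against 20 in the highest other (7 of 10 as large). The other 3 splits that part all 3 same-numbered pairs called 0 intervals. On the high-fat diet the real 795 calls were the highest of 35 splits (1 of 35, highest other 536), so chance is excluded at the 0.05 level. That other split exchanged knockout 1 with floxed 3 and otherwise keeps the genotype groups, so its calls can include the genotype effect. The number of high-fat lists passing was not unusual: 12 of 35 splits gave 11 or more, with 19 as the highest other, so chance is not excluded for that count. For the correlation between diets, the splits used differences of mean log2 CPM, where the real r was 0.0413. Of 350 pairs of splits, 219 gave an absolute value as large, with 0.338 as the highest other. Chance is not excluded there either. Taken list by list on the high-fat diet, the splits with as small a camera p were 1 of 35 for female-biased genes, 1 for cholesterol synthesis, 2 for NRF2 targets, 3 for CAR and PXR targets, 4 for Kupffer cells, 6 for bile acids and for pericentral genes, 11 for fatty acid synthesis, 12 for hepatocyte transcription factors and for the clock, and 22 for periportal genes.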
